A study of Mus musculus with 12 samples.

How the data were processed

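Cells were sorted from the small intestinal lamina propria of germ-free T-bet-ZsGreen mice, marked with hashtags, mixed, and loaded on 4 lanes of a 10x Genomics 5' droplet assay, per the labels' design text. The 12 samples are libraries, 4 each for gene expression, hashtags and T cell receptors, and they were grouped by library type and numbered by lane from their titles. No sample belongs to a single diet. The hashtag names give the diet of each hashtag, and the labels say that hashtags mark biological replicates.

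The deposited files used here hold text and no measured values. They are the list of filtered cell barcodes, the list of features (identifier, name and type) and a table of hashtags (identifier, name, read pattern and barcode). Cell Ranger 7.1.0, R 4.4.2, Seurat 5.1.0 and the mm10 build are named in the submitters' processing notes, without a role or order. The aligner settings, the annotation release and the rule by which barcodes were filtered are not given in the sources used here, and the number of barcodes per lane depends on that rule. In the read patterns listed in the hashtag table, 10 arbitrary bases precede the hashtag barcode.

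Barcodes were split at the hyphen into a 16-base sequence and a suffix from 1 to 4. The suffixes were taken to mark the lanes, since there are 4 of each, and no suffix was matched to a labelled lane. The counts per suffix were compared with equal numbers by a chi-square goodness-of-fit test and pair by pair with two-sided exact binomial tests, adjusted by Benjamini-Hochberg over the 6 pairs at a threshold of 0.05. Lanes are technical repeats of 1 pool, so these p-values compare these lanes over counting error only. Ratios of barcodes to the 40000 loaded cells have 95% Clopper-Pearson intervals, which treat each loaded cell as a separate trial. Counts have exact 95% Poisson intervals. The size of the barcode set was estimated as the summed products of lane sizes over the summed shared sequences. Each pair was tested against the other pairs by an exact binomial test of its part of all shared sequences. On simulated data, 100 draws of lanes of the real sizes from a set of 700000 gave a median estimate of 698027. A pair was called in 3% of these draws when nothing was carried over, and the affected pair was called in 100% when 200 sequences were copied from lane 1 to lane 2.

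Gene identifiers were matched to GENCODE M21, an annotation of GRCm38, the assembly also called mm10. Of the 32285 identifiers 32235 (99.8%) matched, and 31502 had the same symbol there. The listed genes differ in part from that annotation, since 50 identifiers were not in M21. Positions, overlaps and gene classes therefore apply to M21. In the feature list 38 symbols stood for more than 1 identifier, over 78 features. Shared exonic bases were counted over the union of annotated exons of each gene, among listed features. The genes named were those of 11 lists for the studied T cells and 10 lists of cell type markers, fixed before the data were examined. The rule for naming tested genes (the 12 largest changes in each direction per diet comparison) was not used, since no gene was tested.

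The planned diet comparisons needed the matrix of gene and hashtag counts, which was not analysed here. No hashtag assignment, doublet call, clustering or receptor analysis was made. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. The alternatives were leaving out each lane, keeping only sequences of a single lane, allowing 1 mismatch between barcodes, keeping features with a unique symbol, and the edit distance between hashtags.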

Results

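The study asked how diet shapes T-bet-expressing CD4 T cells of the small intestinal lamina propria, the connective tissue layer under the gut epithelium. T-bet, encoded by Tbx21, is the transcription factor that drives the Th1 programme, and the mice carried a ZsGreen fluorescent reporter of T-bet by which the cells were sorted. The animals were germ-free and had been raised on a casein diet, an amino acid diet or regular chow. Biological replicates were marked with a hashtag, an antibody that carries a short DNA barcode, and were then mixed and loaded on 4 lanes of a droplet instrument. Each lane gave 3 libraries, 1 for gene expression, 1 for hashtags and 1 for rearranged T cell receptors, so the series held 12 libraries in 3 groups of 4. Every library mixed all diets. A diet can therefore be assigned only cell by cell, through hashtag counts. The matrix of gene and hashtag counts was not analysed here, so no level of any gene in any diet is given, no UMI total per lane is known, and the diet comparisons were not made. The material examined was the list of cell barcodes that passed filtering, the list of measured features and the list of hashtags.

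The hashtag list held 13 hashtags in 3 diets. Each name carried its own number, and whether each hashtag is a single animal is not stated. Regular chow had 4 hashtags, casein had 5 and the amino acid diet had 4. Each hashtag name also ended in the letter M or F. Chow had 2 hashtags with M and 2 with F, casein had 3 with M and 2 with F, and the amino acid diet had 1 with M and 3 with F. The letters were not detectably uneven across diets at this number of hashtags (Freeman-Halton exact test, two-sided p = 0.79), although only 1 amino acid hashtag carried M. With the hashtag as the replicate and the two-sided p taken as 2 times the one-sided p, an exact permutation test of casein against either other diet has 126 splits and cannot go below p = 0.0159. The same exact test of amino acid against chow has 70 splits and cannot go below p = 0.0286. These floors hold for the permutation test only, which was not the test planned for the diet comparisons. If every filtered barcode were assigned to a single hashtag, the mean would be 4342 barcodes per hashtag, and this is an average of the list and not a measured yield. Among the 78 pairs of 15-base hashtag barcodes the number of differing positions ranged from 7 to 15, with a median of 11. The closest pair by differing positions joined 2 diets: CTTGCCGCATGTCAT, the second chow hashtag (2_Reg_Chow_M), and CTTTCGCCAACTCTG, the amino acid hashtag 11_AminoAcid_F, differed at 7 positions.

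The barcode list held 56451 filtered cell barcodes, which carried 4 suffixes. Suffix 1 had 13819 barcodes, suffix 2 had 14582, suffix 3 had 13595 and suffix 4 had 14455, a mean of 14113 ± 480.2 (SD, n = 4 suffixes). The suffixes were taken to mark the 4 lanes, and which suffix belongs to which labelled lane is not stated. Against the 40000 cells loaded per lane, these numbers came to 34.5% (95% Clopper-Pearson interval 34.1 to 35.0), 36.5% (36.0 to 36.9), 34.0% (33.5 to 34.5) and 36.1% (35.7 to 36.6), in the order of the suffixes. Over all lanes the number of filtered barcodes came to 35.3% of the 160000 loaded cells. A barcode can hold more than 1 cell, and doublets were not assessed. The value is therefore a ratio of barcodes to loaded cells and not a share of cells recovered. The intervals treat each loaded cell as a separate trial, which a barcode with more than 1 cell breaks. At most they cover counting error.

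**Figure D1:**
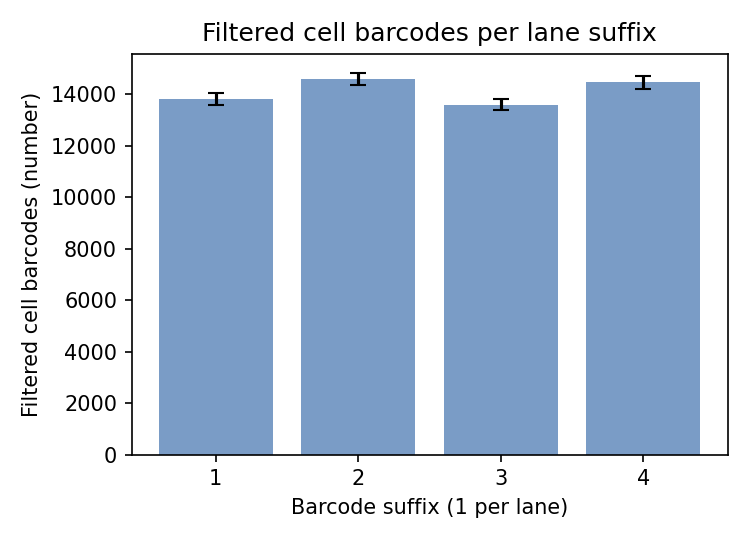
Number of filtered cell barcodes (vertical axis, from 0) for each of the 4 barcode suffixes (horizontal axis). Bars are the counts and error bars are exact 95% Poisson intervals; suffixes 2 and 4, with 14582 and 14455 barcodes, lie above suffixes 1 and 3, with 13819 and 13595.

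The lanes received the same mixed suspension at the same nominal load, so they are technical repeats of 1 pool, and the comparison between them asks whether they gave even numbers of filtered barcodes. The numbers were not even within counting error (chi-square goodness of fit over the 4 counts, statistic 49.0 with 3 degrees of freedom, p = 1.3e-10). Depth per lane and the filtering rule are not known here, so uneven capture, depth and filtering were not separated. The SD of 480.2 exceeded the 119 that counting alone would give, but the spread was small in size, with a coefficient of variation of 3.4%. Suffix 2 had 1.07 times the barcodes of suffix 3 (95% interval 1.05 to 1.10; exact binomial test, two-sided, Benjamini-Hochberg adjusted over 6 pairs, p = 2.54e-08). Suffixes 2 and 4 did not differ detectably over counting error (ratio 1.01, 0.99 to 1.03, exact binomial adjusted p = 0.46). Neither did suffixes 1 and 3 (ratio 1.02, 0.99 to 1.04, exact binomial adjusted p = 0.214). The other 3 pairs passed the test, with suffix 1 at 0.948 of suffix 2 and 0.956 of suffix 4, and suffix 3 at 0.941 of suffix 4.

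Droplet barcodes come from a finite set, so separate lanes share some sequences by chance. The 56451 barcodes held 54854 distinct 16-base sequences, of which 1539 occurred under 2 suffixes, 29 under 3 and 0 under all 4. A total of 3165 barcodes, 5.61% of the list, therefore had a sequence that also stood under another suffix and can be told apart only by that suffix. Each pair of suffixes shared between 258 and 295 sequences, or 1.80% to 2.13% of the smaller lane. If lanes drew independently from 1 set, this sharing corresponds to a set of 734731 sequences (699867 to 771793, from the 95% Poisson interval of the shared number). No pair departed detectably from the number expected from the other 5 pairs: 0 of 6 passed an exact binomial test with Benjamini-Hochberg adjustment, and 0 had an unadjusted p under 0.05. The largest excess was in suffixes 1 and 2, with 295 shared sequences (262 to 331) against 270.1 expected, and the largest deficit was in suffixes 2 and 4, with 260.0 (229 to 294) against 293 expected (exact unadjusted p = 0.0846).

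**Figure D2:**
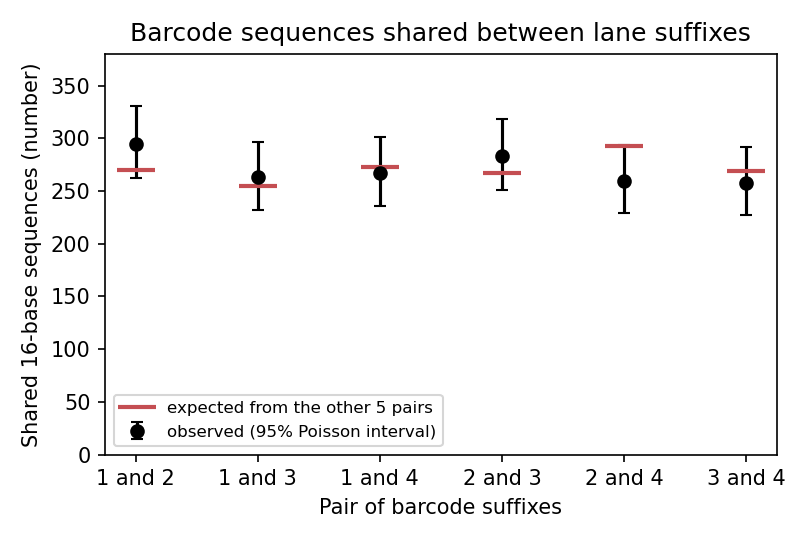
Number of 16-base sequences shared by each of the 6 pairs of barcode suffixes (vertical axis, from 0). Points are observed numbers with exact 95% Poisson intervals and red dashes are the numbers expected from the other 5 pairs; all 6 dashes lie within the intervals, between 254 and 293.

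The feature list defined which genes of these T cells could be counted. It held 32285 genes and the 13 hashtags. By the GENCODE M21 annotation of the mm10 build, 21702 of the genes were protein coding. Another 270 were T cell receptor segments and 427 were immunoglobulin segments, each count including any segments annotated as pseudogenes. A further 6 genes were other pseudogenes, and 9830 were other non-coding genes. The remaining 50 genes were not in M21 and were given no class. The list held 1 of the 9941 processed pseudogenes of the annotation, and 0 of its 2207 microRNA, 1507 small nucleolar RNA and 354 ribosomal RNA genes. It included 13 mitochondrial genes and 242 symbols of the alpha and beta receptor chains, among them 128 Trav, 60 Traj, 35 Trbv and 14 Trbj segments. The ZsGreen reporter by which the cells were sorted was listed under 0 features of that name.

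All 123 genes of the 21 marker lists fixed for this tissue were listed, each under a single identifier. The Tr1 list (type 1 regulatory T cells, which make interleukin 10) had 15 of 15 genes, the Th1 list 10 of 10, the Treg list 8 of 8, the Th17 list 7 of 7, the Th2 list 5 of 5 and the Tfh list 4 of 4. The naive and memory, residency and cytotoxic lists had 7 of 7 each, the cell cycle list 5 of 5 and the immediate early and stress list 6 of 6. The markers of other cells that a sort could carry were also complete, with 4 of 4 for B cells, plasma cells, and innate lymphoid and NK cells, 6 of 6 for epithelium, 5 of 5 for myeloid cells, 3 of 3 for mast cells, gamma delta T cells and stroma, and 2 of 2 for erythroid cells. The pan-T list had 9 of 9. These are counts of listed genes and say nothing of their expression. The feature list held 21702 of the 22028 protein-coding genes of GENCODE M21, so complete marker lists are no result about the tissue or the sort.

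Tbx21 (ENSMUSG00000001444) lies on chromosome 11 from 97098071 to 97115331 on the minus strand of mm10. Il10 (ENSMUSG00000016529), the cytokine that defines Tr1 cells, lies on chromosome 1 from 131019845 to 131024974. Ifng (ENSMUSG00000055170), the main Th1 cytokine, lies on chromosome 10 from 118441046 to 118445892. Lag3 (ENSMUSG00000030124), an inhibitory receptor used as a Tr1 surface marker, lies on chromosome 6 from 124904361 to 124911705, near Cd4 (ENSMUSG00000023274), at 124864692 to 124888221. None of these 5 genes shared exonic bases with another listed feature on either strand.

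Of the 123 genes, 3 shared exonic bases with another listed feature on the same strand. Foxp3 (ENSMUSG00000039521), the transcription factor of regulatory T cells, lies on chromosome X from 7573644 to 7595245 and shared 853 of its 4577 exonic bases, or 18.6%, with the non-coding gene Flicr. Ccr9 (ENSMUSG00000029530), a receptor for homing to the small intestine, lies on chromosome 9 from 123678439 to 123784330 and shared 269 of 10260 bases, or 2.62%, with Gm17200. Gata3 (ENSMUSG00000015619), the Th2 transcription factor, lies on chromosome 2 from 9857078 to 9890034 and shared 77 of 3978 bases, or 1.94%, with 9230102O04Rik. On the opposite strand, 25 of the 123 genes shared exonic bases with a listed feature, Foxp3, Maf, Eomes and Ahr among them. Overlaps were counted for the 123 genes only, so whether these numbers differ from those of all listed features is not known. Whether overlap on either strand affects any count was not tested. The percentages are shares of annotated exonic bases and not of reads, and the position of each overlap in its gene was not examined. How the authors' counting treated strand and shared bases is not given in the sources used here.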

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

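The uneven number of barcodes per lane passed the chi-square test under every alternative run: the statistic was 51.9 with only sequences of a single lane and 23.4 to 40.6 when 1 lane was left out, against 49.0 with all lanes. The number of sequences found under 2 or more suffixes was 1568, and allowing 1 mismatch could not change it, since 0 pairs of sequences differed at 1 base. It fell to between 778 and 827 when a lane was left out, since fewer pairs of lanes remain, and no pair passed the test of its shared number in any of these settings. The list held 32285 genes, and 32207 had a unique symbol. The smallest distance between hashtags was 7 by differing positions and 6 by edit distance, which also allows insertions and deletions, and the closest pairs changed with it: 5_Casein_M with 13_AminoAcid_F and 2_Reg_Chow_M with 9_Casein_F were at edit distance 6, against 7 for 2_Reg_Chow_M with 11_AminoAcid_F. The alternatives planned for the diet comparisons (another normalization, no filter on low counts, leaving out each mouse) were not run. No paired analysis was possible because the groups are kinds of library from the same lanes and no file used here gives values per library. Barcode lists carry no read depth, so the precision of any gene level is unknown.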

Other observations

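The tests of a repeated lane library, of sequences under 3 suffixes and of 1-base spacing were chosen after the result was seen, while the count of shared sequences was planned. No biological explanation was tested, because the lanes are repeats of 1 pool and the design gives them no biological difference. A lane library that had entered the list again under another suffix would share most of its sequences with the other lane, and the most that any pair of lanes shared was 2.13% of the smaller lane, which argues against it. A small carry-over of equal size between all lanes would only lower the estimated set size and stays open. A carry-over within 1 pair of lanes was simulated at 200 sequences only, so a smaller one stays open too.

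The 29 sequences under 3 suffixes compare with 20.6 ± 4.53 (SD) in 2000 simulated equal draws from a set of the estimated size. A candidate explanation is that some barcodes are more frequent than others in the set, which would raise sharing across 3 lanes more than across 2. The call depends on the side of the test: from simulated draws, not an exact test, the two-sided p was 0.097 and the one-sided p, for the direction this explanation predicts, was 0.0485. The draws held the set at its estimated size, so both p-values leave out the error of that estimate. The side was chosen after the count was seen, so equal and unequal frequencies cannot be told apart with 4 lanes.

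Among the 54854 distinct sequences, 0 pairs differed at a single base, where 16.8 pairs would be expected among random sequences of the same length (Poisson probability of 0 pairs, 4.99e-08). This argues against sequences that are unrestricted in their spacing. Whether the spacing belongs to the barcode set or to the filtering was not tested.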
